A study of Homo sapiens with 12 samples.

How the data were processed

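Messenger RNA was measured by sequencing in 12 libraries of human primary hepatic stellate cells, the liver's pericyte-like cells that turn into matrix-producing myofibroblasts during fibrosis. Per the labels' protocols, cells were transduced for 48 h with lentivirus carrying a control short hairpin RNA (shRNA) or shRNA against synectin, the PDZ-domain adaptor protein encoded by GIPC1. They were then selected in puromycin for 24 h, kept for a further 24 to 48 h in medium with 10% fetal bovine serum, starved overnight and treated with vehicle or with platelet-derived growth factor BB (PDGF) at 10 ng/ml for 2 h. The labels name 2 shRNA clones against synectin without their sequences and without saying which library received which. Total RNA was taken up in Trizol, purified on columns and 1 µg entered a standard Illumina messenger RNA library, per the labels.

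Per the submitters' processing notes, base calling used CASAVA 1.9, reads were aligned to hg19 and reads per gene were counted with HTSeq. The deposited table gives 57773 features with an Ensembl identifier, a symbol, hg19 coordinates and a coding length, and per library a raw read count and an RPKM value (the count scaled to gene length and library size) that the authors computed from it. All tests here start from the deposited counts. The RPKM values were used only to check the counts, and the strand setting of the counting is not given in the sources used here, so overlapping genes on opposite strands are not told apart.

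Libraries were grouped by their titles into 4 groups of 3: control shRNA with vehicle (libraries 1, 4 and 7), control shRNA with PDGF (2, 5 and 8), synectin shRNA with vehicle (10, 13 and 16) and synectin shRNA with PDGF (11, 14 and 17). The labels' genotype field contradicts the titles in 6 libraries, since it follows the PDGF treatment and not the shRNA. The GIPC1 level in each library goes with the titles. The labels do not say whether the 3 libraries of a group are separate cultures, so p-values measure only the spread between these samples.

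Counts were scaled by the trimmed mean of M-values (TMM) and analysed with edgeR 4.0.16 in R 4.3.3. Of 39668 features with a count, 21344 passed the low-count filter (filterByExpr with a minimum count of 10 and a minimum total of 15). A model with 1 mean per group was fitted to all 12 libraries with robust quasi-likelihood dispersions. edgeR's quasi-likelihood F test, two-sided, gave 5 comparisons: synectin against control shRNA in vehicle, the same in PDGF, PDGF against vehicle under control shRNA, the same under synectin shRNA, and the interaction, which is the PDGF response under synectin shRNA minus that under control shRNA. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are TMM-normalised CPM (counts scaled to library size), computed from the deposited counts and given as mean ± SD over 3 libraries, and fold changes and standard errors of log2 fold changes come from the fitted model. Standard errors of a median or mean over a set of genes, and z of sequence motifs, are taken over genes. Genes are not independent replicates, so these do not measure the spread between libraries.

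Which genes are named, the 26 gene lists, the model and the alternatives were fixed before the data were examined. GIPC1, PDGFRA and PDGFRB are always reported. Per comparison, the 8 largest increases and the 8 largest decreases are eligible among called genes whose groups do not overlap in CPM and whose mean is at least 5 CPM, leaving out clone, non-coding and pseudogene symbols. For the interaction these are 5 and 5 without the overlap rule. From each list up to 4 called members are eligible, smallest adjusted p ahead, or up to 2 of the highest mean CPM where none was called. Genes whose call depends on 1 library are mostly left unnamed. The lists are PDGF receptors and ligands, synectin family and known binding partners, myofibroblast contractile and cytoskeletal genes, collagens and fibrotic matrix, matrix cross-linking and remodelling enzymes, TGF-beta pathway and targets, immediate-early genes, ERK feedback regulators, inflammatory cytokines and NF-kappaB targets. They continue with YAP and SRF-MRTF targets, cell cycle and proliferation, p53 and growth arrest, interferon response, unfolded protein and amino acid stress response, autophagy and lysosome, endocytic trafficking. The rest are histone acetylation and methylation enzymes, cholesterol and fatty acid synthesis, oxidative phosphorylation, cytosolic ribosomal proteins, quiescent stellate cell markers, activated stellate cell and portal fibroblast markers, and markers of hepatocytes, endothelial cells, macrophages and leukocytes, and cholangiocytes and epithelium. Of 704 list entries, 702 matched a symbol in the table, and PECAM1 and CD24 did not. Some lists share members, so their results are not independent. ACTA2, TAGLN, MYL9, VCL and TPM1 are in the contractile and the YAP and SRF-MRTF lists. SRF is in the contractile and immediate-early lists, IER3 in the immediate-early and ERK feedback lists and LIF in the ERK feedback and inflammatory lists. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and on their own with fry, each adjusted over the 26 lists of a comparison. Counts of called members are given over all genes tested and, after them in the same order, adjusted over the list alone, which is left out where the 2 counts were equal.

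Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), median-ratio (RLE) and upper-quartile factors, library totals only, no low-count filter, a stricter filter of at least 1 CPM in 6 libraries, fits to the 6 libraries compared, an adjusted p of 0.01, a fold of at least 2, a block of adjacent title numbers, and leaving out each library in turn. A limma-voom fit with sample quality weights was added after the data were seen.

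The gene tests, and the list tests for the knockdown in vehicle, were run on simulated counts drawn from the real means and library sizes, with known folds in 200 genes. The other steps were not run on simulated counts. edgeR recovered 69.7% of 2-fold changes for the knockdown in vehicle (20944 genes), 66.2% for the knockdown in PDGF (20953 genes), 68.7% for PDGF under control shRNA (20877 genes), 60.6% for PDGF under synectin shRNA (20908 genes) and 29.2% for the interaction (20906 genes). The interaction test is therefore the least sensitive of the 5. In the same counts 3.31% to 9.70% of edgeR's calls were false by comparison (7.81% for the interaction), against 21.1% to 31.6% of those of DESeq2.

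Smooth curves of gene length and GC content were fitted with mgcv 1.9.3, and sequence counts were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, on transcript sequences of a GRCh38 annotation joined by gene identifier, and no coordinate of that build is used. Figures were drawn with matplotlib 3.10.9. Nothing was left out of the 12 libraries. Library 16 departs from the other members of its group. Leaving it out raises the number of genes called in all 5 comparisons and the number of called members in most lists, and only some of these list counts are given.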

Results

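Messenger RNA was sequenced in primary human hepatic stellate cells, the cells that lay down scar matrix in the injured liver, with and without knockdown of synectin and with and without 2 h of PDGF. The 12 libraries form 4 groups of 3: control shRNA with vehicle, control shRNA with PDGF, synectin shRNA with vehicle and synectin shRNA with PDGF. Their gene counts summed to 46077552 to 62936992 reads per library. The study asks how loss of synectin, an adaptor that binds receptor tails and helps move them through the cell, bears on PDGF receptor signalling and liver fibrosis. On a principal component plot of log2 CPM, component 1 (37.1% of variance) separated the shRNAs, and library 16 (synectin shRNA, vehicle) lay apart from libraries 10 and 13.

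**Figure D1:**
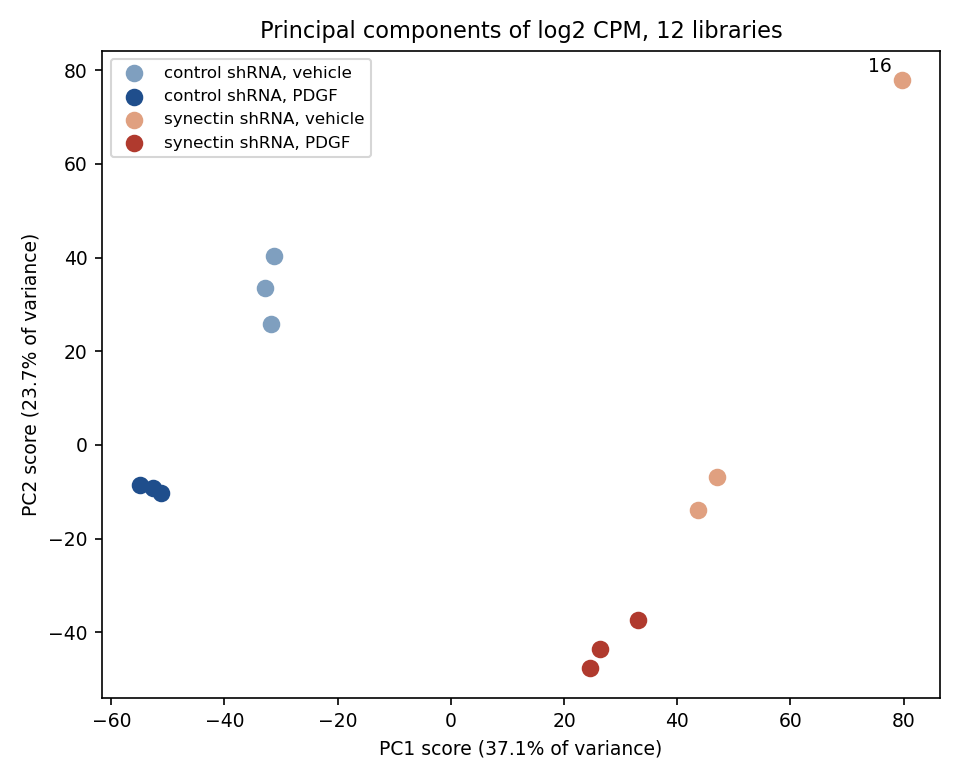
Principal component scores of log2 CPM for the 12 libraries, component 1 (37.1% of variance) on the horizontal and component 2 (23.7%) on the vertical axis, coloured by group. The shRNAs part along component 1, and library 16 is marked because it sits far from the other synectin shRNA libraries in vehicle.

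Synectin mRNA was lower in each synectin shRNA library than in each control library. GIPC1 (ENSG00000123159, hg19 chromosome 19, 14588572 to 14606944) stood at 81.9, 82.7 and 97.4 CPM in the control vehicle libraries and at 74.6, 78.0 and 84.0 CPM in the control PDGF libraries. It stood at 16.8, 16.1 and 32.0 CPM in synectin shRNA libraries 10, 13 and 16, and at 14.1, 14.5 and 14.1 CPM in the synectin shRNA PDGF libraries. The knockdown was 4.04-fold in vehicle (87.3 ± 8.73 against 21.6 ± 8.96 CPM, SD, n = 3, log2 fold change -2.01, SE 0.22, adjusted p = 6.5e-05) and 5.54-fold in PDGF (78.9 ± 4.76 against 14.2 ± 0.208 CPM, -2.47, SE 0.23, adjusted p = 1.7e-05). PDGF itself did not give a call for GIPC1 under control shRNA (adjusted p = 0.796) or under synectin shRNA (adjusted p = 0.121, or 0.0471 without library 10 and 0.0482 without library 13).

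The beta receptor for PDGF was lower with synectin shRNA. PDGFRB (ENSG00000113721, hg19 chromosome 5, 149493400 to 149535435) is the tyrosine kinase through which PDGF-BB drives stellate cell growth and migration. It went from 713 ± 11.5 to 189.6 ± 62.1 CPM in vehicle (3.76-fold lower, log2 fold change -1.91, SE 0.20, adjusted p = 4.6e-05, n = 3 libraries per group). In PDGF it went from 641 ± 26.2 to 236 ± 10.2 CPM (2.72-fold lower, -1.44, SE 0.20, adjusted p = 0.000317). PDGFRA (ENSG00000134853, hg19 chromosome 4, 55095264 to 55164414) is the alpha isoform. In vehicle it averaged 629 ± 49.9 CPM in control and 424 ± 177 CPM in synectin shRNA cells, a difference that did not pass (adjusted p = 0.108, or 0.0113 without library 13). Library 16 held 242 CPM against 435 and 594 in libraries 10 and 13. In PDGF the alpha receptor averaged 427 ± 28.3 CPM in control and 308 ± 33.5 CPM in synectin shRNA cells (adjusted p = 0.193). Without library 16, whose spread enters every test, the PDGFRA difference in PDGF passed (adjusted p = 0.0082). The drop of PDGFRA with PDGF passed without library 16 in control (adjusted p = 0.0048) and in synectin shRNA cells (adjusted p = 0.0023), against 0.189 and 0.266 with all libraries. PDGFRB with PDGF under control shRNA likewise moved from adjusted p = 0.753 to 0.023.

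**Figure D2:**
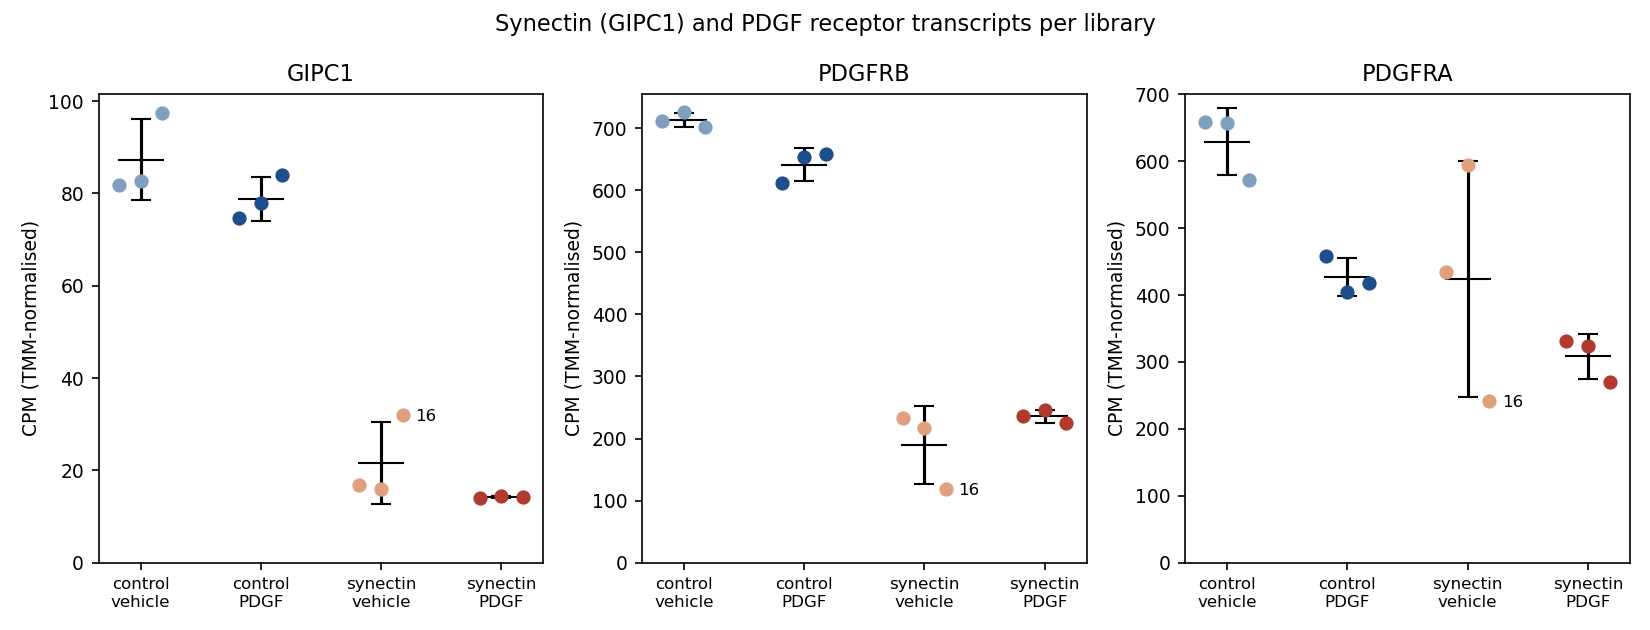
TMM-normalised CPM of GIPC1, PDGFRB and PDGFRA (vertical axes) in the 12 libraries by group; points are libraries, horizontal bars group means and error bars 1 SD (n = 3). All synectin shRNA libraries lie at or below 246 CPM for PDGFRB and all control libraries at or above 611 CPM.

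In unstimulated cells, contractile genes were lower with synectin shRNA. By the preset test alone, matrix genes were lower and interferon-response genes higher as groups (adjusted p = 0.384 and adjusted p = 0.299 with an estimated correlation). The largest decreases were in KIAA1199, a hyaluronan-degrading protein (341 ± 7.94 to 21.9 ± 10.1 CPM, 15.6-fold), SLC6A9, a glycine transporter (65.3 ± 2.97 to 5.55 ± 1.01 CPM, 11.8-fold), and DAP, a death-associated autophagy regulator (341 ± 13.9 to 33.2 ± 2.15 CPM, 10.3-fold, n = 3). They were followed by cardiac troponin TNNT2 (9.02-fold) and the basement membrane collagen COL15A1 (8.61-fold). The largest increases were in the granin SCG2 (1.06 ± 0.260 to 12.6 ± 3.50 CPM, 11.9-fold) and the lipase inhibitor ANGPTL4 (4.09 ± 0.531 to 44.6 ± 18.5 CPM, 10.9-fold). Next came the interferon-induced antiviral genes BST2 (10.7-fold), MX1 (9.87-fold) and IFI44L (9.13-fold). Adjusted p for these genes ranged from 5.2e-08 for DAP to 0.000997 for BST2. In all, 2906 genes were higher and 2787 lower of 21344 tested. Leaving out library 16 raised the total from 5693 to 9986, and 5527 genes kept their call and direction. With library totals in place of TMM the split moved from 51.0% to 68.6% higher (4689 against 2144), as that scaling shifted the median of all genes from 0.07 to 0.19 on the log2 scale.

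Contractile genes fell as a group in vehicle. Of 20 myofibroblast contractile genes, 14 were lower and 0 higher (16 and 0 when adjusted over the list alone, camera adjusted p = 5.3e-10, adjusted p = 0.0024 with an estimated correlation, or 0.0734 without library 16). SRF, the transcription factor that drives actin genes, fell 3.39-fold (51.2 ± 0.569 to 15.1 ± 0.536 CPM) and leiomodin LMOD1 6.96-fold. Smooth muscle actin ACTA2, the standard mark of an activated stellate cell, fell 4.51-fold (from 453 to 100.4 CPM, log2 fold change -2.17, SE 0.17) and enteric smooth muscle actin ACTG2 4.53-fold. Among 35 collagen and matrix genes 17 were lower and 3 higher (19 and 3 adjusted over the list alone, adjusted p = 1.8e-05, but adjusted p = 0.384 with an estimated correlation). Without library 16, in which 28 of them lay below both other members of its group, 21 were lower and 9 higher, and the median moved from -0.52 to -0.30 (adjusted p = 0.0028). Periostin POSTN, a matrix protein of scars, went the other way (111 ± 4.98 to 353 ± 20.4 CPM, 3.17-fold higher). Fibulin FBLN5 (2.03-fold), decorin DCN (2088 ± 30.7 to 600.3 ± 142 CPM, 3.48-fold) and thrombospondin THBS2 (2.75-fold) fell. GREM1, the secreted BMP antagonist of activated stellate cells and portal fibroblasts, went from 2426 ± 7.93 to 541 ± 5.28 CPM (4.48-fold lower, adjusted p = 1.1e-07). YAP and SRF-MRTF targets, which share ACTA2 and other members with the contractile list, fell too, 13 lower and 2 higher of 25 (15 and 2 adjusted over the list alone, adjusted p = 5.5e-05, adjusted p = 0.054 with an estimated correlation), with NT5E 2.52-fold higher.

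Sterol and fatty acid synthesis genes were lower in vehicle as well. Of 33 cholesterol and fatty acid synthesis genes 18 were lower and 0 higher (23 and 1 adjusted over the list alone, adjusted p = 5.3e-10, adjusted p = 0.0153 with an estimated correlation, or 0.215 without library 16). The sterol sensor INSIG1 fell 5.10-fold. The master regulator SREBF2 fell 6.03-fold (144 ± 4.62 to 23.8 ± 5.62 CPM). The unfolded protein and amino acid stress list had 18 lower and 1 higher of 29 (18 and 2 adjusted over the list alone, adjusted p = 9.6e-07, adjusted p = 0.299 with an estimated correlation, or 0.0038 without library 16). The lipoprotein receptor VLDLR (2.40-fold), the leucine transporter SLC7A5 (3.37-fold), the serine synthesis enzyme PSAT1 (2.87-fold) and the pseudokinase TRIB3 (3.05-fold) were lower.

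Interferon-response genes rose almost as a whole in vehicle: 29 of 32 were higher and 0 lower (30 and 0 adjusted over the list alone, adjusted p = 2.7e-13, adjusted p = 0.299 with an estimated correlation). IRF9, part of the interferon-activated transcription complex, went from 25.3 ± 0.323 to 66.6 ± 10.9 CPM (2.64-fold), and USP18, which restrains interferon signalling, rose 2.86-fold. The p53 and growth arrest list also rose, 9 higher and 1 lower of 27 (the same adjusted over the list alone, adjusted p = 0.0022, adjusted p = 0.299 with an estimated correlation), or 14 and 5 without library 16 (adjusted p = 0.039). It was led by the BH3-only protein PMAIP1 (27.6 ± 1.35 to 70.3 ± 6.68 CPM, 2.55-fold). PDGF receptors and ligands had 4 of 10 lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.0288, adjusted p = 0.167 with an estimated correlation, and 0.0523 by the preset test without library 7).

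The other lists did not pass as groups in vehicle, though single members moved far. ERK feedback regulators had 11 higher and 5 lower of 27 (13 and 5 adjusted over the list alone, adjusted p = 0.116). The phosphatase DUSP4 was 4.13-fold higher and the feedback protein PHLDA1 4.50-fold (182 ± 2.92 to 818 ± 114 CPM). Immediate-early genes had 12 higher and 4 lower of 30 (12 and 6 adjusted over the list alone, adjusted p = 0.170). Inflammatory genes had 3 higher and 9 lower of 31 (3 and 11, adjusted p = 0.105), and the adhesion molecule VCAM1 fell 4.10-fold. Matrix enzymes had 11 higher and 11 lower of 32 (13 and 12, adjusted p = 0.831). The protease ADAMTS1 fell 2.77-fold and the collagen lysyl hydroxylase PLOD1 2.88-fold, and the urokinase PLAU rose 2.78-fold. TGF-beta pathway genes had 6 higher and 5 lower of 26 (7 and 6, adjusted p = 0.693), or 11 and 8 without library 16. Cell cycle genes had 3 higher and 9 lower of 36 (5 and 9, adjusted p = 0.123, or 0.033 without library 13), with cyclin D1, CCND1, at 971 ± 11.7 and 1944 ± 190.2 CPM. The synectin family and binding partners had 1 higher and 4 lower of 16 (adjusted p = 0.205), or 4 and 7 without library 16. Among them were the integrin ITGA6 (1.64-fold higher) and the neuropilin NRP2 (201 ± 8.45 to 72.1 ± 27.7 CPM, 2.79-fold lower).

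Organelle lists and cell type markers did not pass as groups in vehicle. Autophagy and lysosome genes had 5 higher and 11 lower of 42 (5 and 12 adjusted over the list alone). With all libraries camera pointed down (adjusted p = 0.454) while the median was 0.03. Without library 16 the list passed (adjusted p = 0.029), but had adjusted p = 0.590 with an estimated correlation. Endocytic trafficking had 2 higher and 5 lower of 38 (adjusted p = 0.826) and histone-modifying enzymes 3 higher and 5 lower of 33 (4 and 6, adjusted p = 0.454), and the lysine methyltransferase SETD7 fell 3.75-fold. Without library 16 these counts were 10 and 9 for endocytic trafficking and 14 and 8 for histone-modifying enzymes. Oxidative phosphorylation had 1 higher and 1 lower of 33 (0 and 0 adjusted over the list alone, adjusted p = 0.196, but 0.0041 without library 10, 0.0298 without 13 and, in the other direction, 0.0296 without 16). No ribosomal protein gene of 37 was called by edgeR, DESeq2 or limma-voom, or had an unadjusted p under 0.05 by edgeR (adjusted p = 0.196 for the list), whereas without library 16 all 37 were lower (2.3e-15). Without library 16 these 2 lists had adjusted p = 0.667 and adjusted p = 0.400 with an estimated correlation. Quiescent stellate cell markers had 4 higher and 2 lower of 13 (adjusted p = 0.826) and activated ones 3 higher and 5 lower of 15 (4 and 5 adjusted over the list alone, adjusted p = 0.454). Marker lists had 1 higher and 0 lower of 5 for hepatocytes (adjusted p = 0.293) and 0 and 1 of 9 for endothelium (0.826). They had 0 and 2 of 5 for macrophages and leukocytes (0.170) and 3 and 0 of 11 for cholangiocytes and epithelium (0.489), which without library 16 had 2 higher and 5 lower, the median moving from 0.05 to -0.26.

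**Figure D3:**
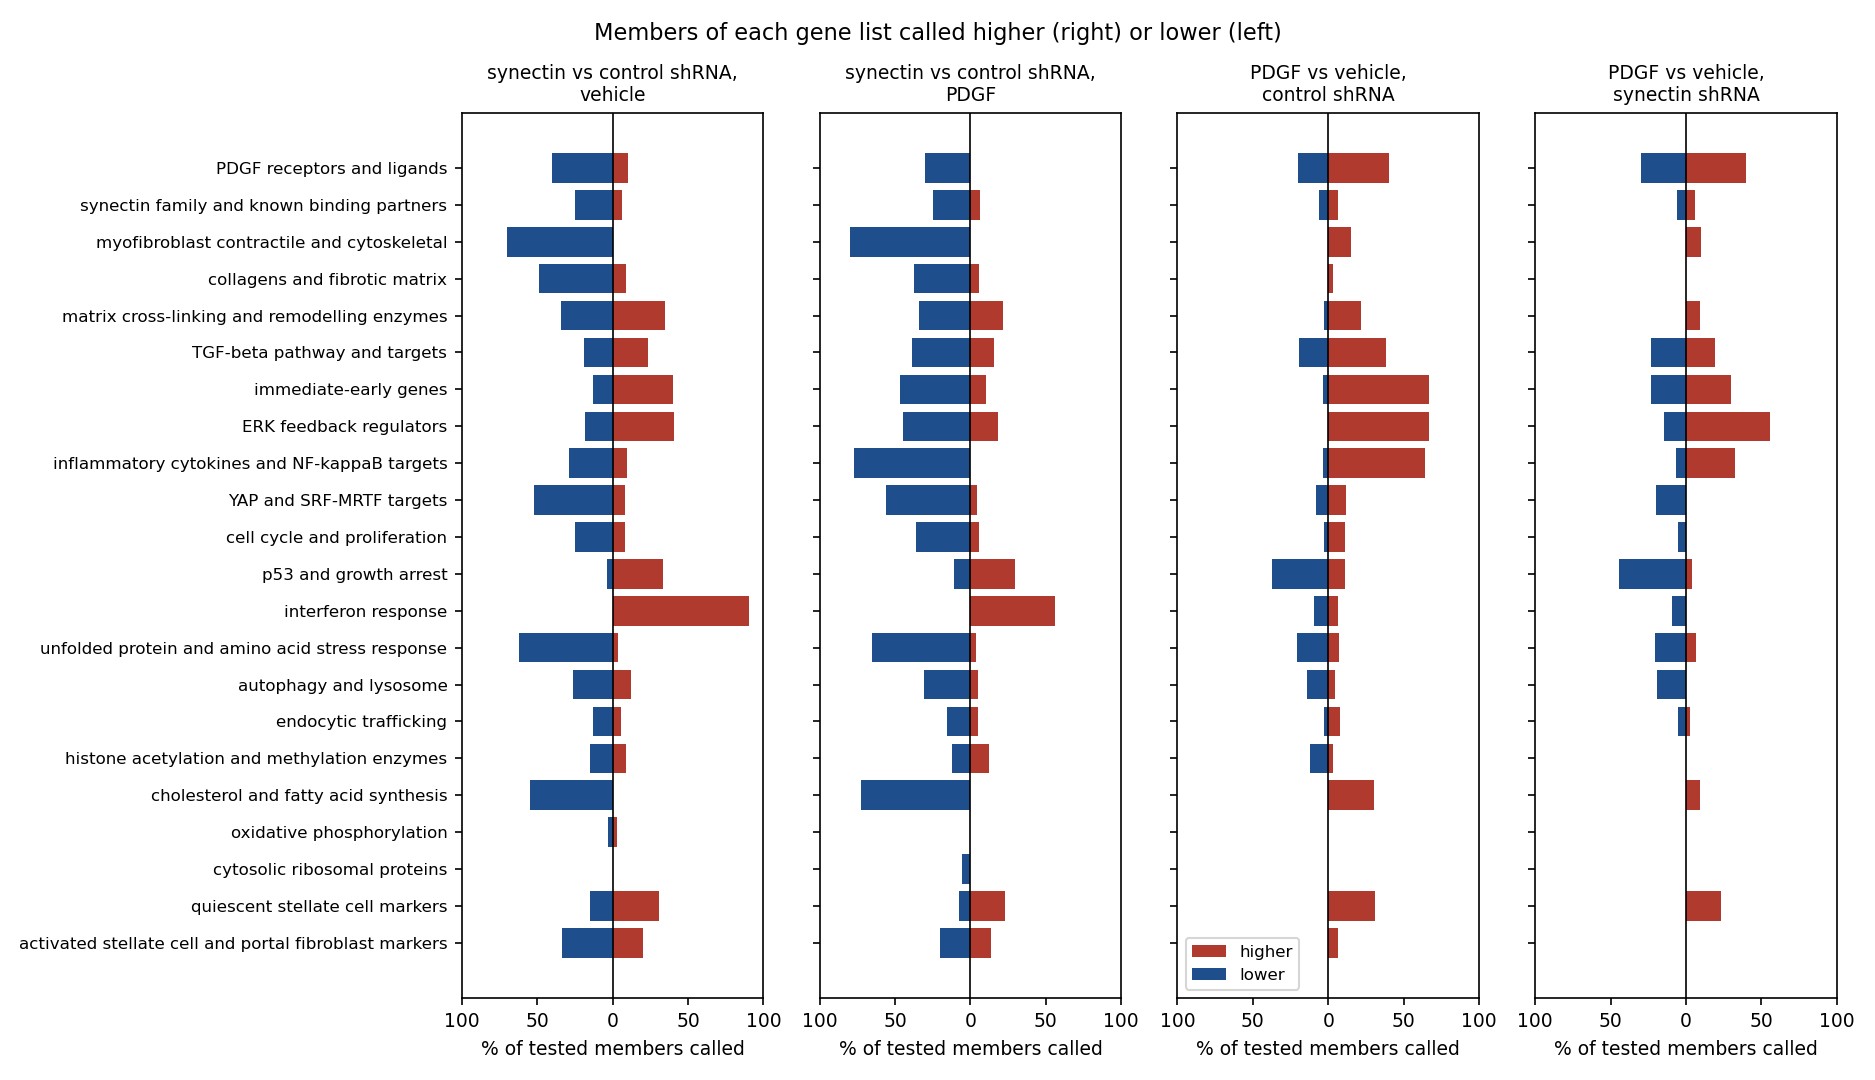
Percent of the tested members of 22 gene lists called higher (bars to the right) or lower (bars to the left) in each of 4 comparisons. Interferon-response genes reach furthest to the right and contractile genes furthest to the left under synectin shRNA, and the immediate-early, ERK feedback and inflammatory lists reach right with PDGF.

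With PDGF present, the contractile and sterol lists were again lower with synectin shRNA, and so were inflammatory genes. INSIG1 fell 15.2-fold (82.4 ± 7.11 to 5.43 ± 0.987 CPM, n = 3, log2 fold change -3.92, SE 0.14, adjusted p = 2.9e-08). SLC6A9 fell 14.2-fold, TNNT2 13.6-fold and DAP 11.1-fold. The largest increases were in BMF, a pro-apoptotic BH3-only protein (1.52 ± 0.238 to 9.77 ± 1.01 CPM, 6.39-fold), and the collagen COL24A1 (5.56-fold). Next came the integrin ITGB8, which activates latent TGF-beta (15.6 ± 1.86 to 84.4 ± 4.78 CPM, 5.42-fold), and the histone gene HIST1H2BC (5.05-fold), whose reads can be shared with near-identical copies. In all, 2234 genes were higher and 2829 lower. Without library 16, which takes no part in this contrast but adds to the pooled spread, the total rose from 5063 to 10858, and 5057 genes kept their call and direction. The higher share was 44.1% with TMM, 54.3% with upper-quartile factors (2882 against 2427) and 66.4% with library totals (4002 against 2026), which shifted the median of all genes from 0.02 to 0.18.

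Inflammatory genes were broadly lower with PDGF present, 24 lower and 0 higher of 31 (27 and 0 adjusted over the list alone, adjusted p = 1.1e-14, adjusted p = 0.0169 with an estimated correlation, or 0.137 without library 16). VCAM1 fell 4.52-fold, the mitochondrial superoxide dismutase SOD2 3.01-fold and interleukin 11, IL11, a profibrotic cytokine, 7.38-fold (145 ± 16.6 to 19.7 ± 3.79 CPM). Contractile genes had 16 lower and 0 higher of 20 (17 and 0, adjusted p = 3.2e-11, adjusted p = 0.0017 with an estimated correlation, or 0.0572 without library 16). SRF fell 6.39-fold (93.4 ± 3.87 to 14.6 ± 1.60 CPM), LMOD1 9.69-fold and ACTA2 5.72-fold (452 ± 55.7 to 79.0 ± 0.296 CPM). Cholesterol and fatty acid synthesis had 24 lower and 0 higher of 33 (the same adjusted over the list alone, adjusted p = 3.1e-15, adjusted p = 0.0033 with an estimated correlation, or 0.136 without library 16). YAP and SRF-MRTF targets had 14 lower and 1 higher of 25 (16 and 2, adjusted p = 2.4e-07, adjusted p = 0.0157 with an estimated correlation, or 0.246 without library 16). Tissue factor F3 was 5.14-fold lower (144 ± 5.53 to 28.0 ± 3.71 CPM). In collagens and matrix 13 were lower and 2 higher of 35 (14 and 3, adjusted p = 0.0081, but adjusted p = 0.516 with an estimated correlation), and without library 16 there were 20 and 8. POSTN was again higher, at 383 ± 9.77 against 109 ± 5.60 CPM, and DCN 4.03-fold lower.

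Immediate-early genes had 14 lower and 3 higher of 30 in PDGF (17 and 3 adjusted over the list alone, adjusted p = 5.9e-05, adjusted p = 0.107 with an estimated correlation). After SRF, the growth regulator MYC fell 3.20-fold (86.7 ± 3.25 to 27.1 ± 1.85 CPM) and the matricellular protein CYR61 4.99-fold. ERK feedback regulators had 12 lower and 5 higher of 27 (13 and 6, adjusted p = 0.0764). HBEGF, a membrane-anchored EGF receptor ligand, fell 8.34-fold (121 ± 8.25 to 14.5 ± 0.867 CPM) while DUSP4 rose 3.28-fold. The stress response list had 19 lower and 1 higher of 29 (21 and 1, adjusted p = 2.4e-09, adjusted p = 0.169 with an estimated correlation, or 0.0041 without library 16). Cell cycle had 13 lower and 2 higher of 36 (17 and 3, adjusted p = 0.0013, adjusted p = 0.321 with an estimated correlation) and autophagy and lysosome 13 lower and 2 higher of 42 (13 and 3, adjusted p = 0.0179, adjusted p = 0.461 with an estimated correlation). Ribosomal protein genes had 2 lower of 37 (0 adjusted over the list alone, adjusted p = 7.6e-05, adjusted p = 0.600 with an estimated correlation), and without library 16 all 37 were called lower at the same median of -0.51. Interferon-response genes were higher here as well, 18 of 32 with 0 lower (22 and 0, adjusted p = 4.8e-08, adjusted p = 0.371 with an estimated correlation). PDGF receptors and ligands had 3 lower of 10 (adjusted p = 0.0519, and 0.0489, 0.0476, 0.0482, 0.0325 and 0.0432 without libraries 1, 7, 8, 11 and 13). The p53 and growth arrest list had 8 higher and 3 lower of 27 (adjusted p = 0.0519, or 0.0268 without library 14). Oxidative phosphorylation (adjusted p = 0.342, or 0.0394 without library 16, where adjusted p = 0.646 with an estimated correlation) and the remaining 11 lists, from TGF-beta pathway (adjusted p = 0.0995) to endothelial markers (adjusted p = 0.982), did not pass.

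The knockdown effects with and without PDGF correlated across genes. Over 21344 genes the log2 fold changes of these 2 contrasts, which share no library, gave Pearson r = 0.72 (0.213 without the low-count filter) and Spearman rho = 0.67; genes are not independent replicates. Of the called genes 1535 were higher and 2008 lower in both, where independent lists would share 304 and 369, and 33 went opposite ways. Both contrasts use 1 fit with the same spread per gene, so calls can coincide more often than in independent lists even where effects are unrelated.

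PDGF on its own raised ERK feedback, inflammatory and immediate-early genes within 2 h in control cells. The actin-binding XIRP1 went from 0.242 ± 0.141 to 17.3 ± 1.39 CPM (73.3-fold, n = 3) and the prostaglandin synthase PTGS2 from 0.533 ± 0.205 to 25.3 ± 4.21 CPM (46.2-fold). The nuclear receptor NR4A3 rose 36.4-fold, MALL 27.5-fold and HBEGF 24.8-fold (4.86 ± 0.271 to 121 ± 8.25 CPM, log2 fold change 4.63, SE 0.16, adjusted p = 3.8e-08). PDGFB, which encodes the PDGF-B chain itself, rose 23.7-fold (0.571 ± 0.221 to 13.3 ± 0.636 CPM) and IL11 23.4-fold. Among the genes that fell were the ubiquitin ligase FBXO32 (28.1 ± 0.704 to 2.57 ± 0.124 CPM, 10.9-fold), the kinase PIM1 (9.45-fold) and the mTOR inhibitor DDIT4 (9.12-fold). BMF fell 8.55-fold and TXNIP, a brake on glucose uptake, 7.81-fold (247 ± 0.838 to 31.6 ± 5.77 CPM). In all, 1665 genes were higher and 990 lower. The total of 2655 rose to 7233 without library 16, with 2654 genes keeping call and direction. It dropped to 1662, 1579 and 1762 without control vehicle libraries 1, 4 and 7, and to 1665, 1719 and 1698 without control PDGF libraries 2, 5 and 8.

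ERK feedback regulators rose with PDGF in control cells, 18 higher and 0 lower of 27 (19 and 0 adjusted over the list alone, adjusted p = 5.2e-17, adjusted p = 0.00027 with an estimated correlation). After HBEGF, the ERK antagonist SPRY2 rose 7.18-fold (7.07 ± 0.330 to 50.7 ± 2.40 CPM) and the EGF receptor inhibitor ERRFI1 4.66-fold. Inflammatory genes had 20 higher and 1 lower of 31 (24 and 1, adjusted p = 5.2e-17, adjusted p = 0.0141 with an estimated correlation, or 0.102 without library 16). Immediate-early genes had 20 higher and 1 lower of 30 (24 and 1, adjusted p = 2.4e-16, adjusted p = 0.0064 with an estimated correlation, or 0.0594 without library 16), with KLF6 3.71-fold, NR4A1 20.3-fold and MYC 2.82-fold higher. Sterol genes rose, 10 higher and 0 lower of 33 (12 and 0, adjusted p = 0.00023, adjusted p = 0.0946 with an estimated correlation). They were led by the synthase HMGCS1 (1.78-fold) and INSIG1 (2.32-fold). The p53 and growth arrest list fell, 10 lower and 3 higher of 27 (10 and 6, adjusted p = 0.0046, adjusted p = 0.334 with an estimated correlation). The cell cycle inhibitor CDKN1B fell 3.65-fold and TP53INP1 6.94-fold. Autophagy and lysosome had 6 lower and 2 higher of 42 (9 and 2, adjusted p = 0.0291, but 0.0541 without library 2 and 0.0646 without 7, adjusted p = 0.676 with an estimated correlation). Cholangiocyte and epithelial markers had 4 higher and 1 lower of 11 (5 and 1, adjusted p = 0.0037, adjusted p = 0.158 with an estimated correlation). Among them was the transcription factor SOX9 (26.0 ± 1.14 to 183 ± 2.20 CPM, 7.02-fold).

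Fibrosis lists did not pass as groups within 2 h of PDGF in control cells. Collagens and matrix pointed down (median -0.13, adjusted p = 0.0505) with 1 gene of 35 called, elastin ELN, which was higher (1.65-fold). Without library 16, 16 were lower and 2 higher, and the list passed without libraries 1 (0.0447), 8 (0.0373), 10 (0.0419), 13 (0.0422) or 16 (0.0048), but had adjusted p = 0.875 with an estimated correlation, or 0.556 without library 16. Contractile genes had 3 higher of 20 (adjusted p = 0.172), SMTN 2.27-fold, SRF 1.82-fold (51.2 ± 0.569 to 93.4 ± 3.87 CPM) and desmin DES 3.77-fold. TGF-beta pathway genes went both ways, 10 higher and 5 lower of 26 (adjusted p = 0.565, camera up, median slightly below 0), with the activin subunit INHBA 4.42-fold higher. Among PDGF receptors and ligands 4 were higher and 2 lower of 10 (4 and 3, adjusted p = 0.742, median -0.18 while camera pointed up), PDGFA rising 4.10-fold after PDGFB. Ribosomal protein genes had 0 of 37 called by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05 (adjusted p = 0.463, or 0.0140 without library 16, where adjusted p = 0.919 with an estimated correlation), and the remaining 14 lists had adjusted p from 0.146 for quiescent markers to 0.972 for endocytic trafficking.

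In synectin shRNA cells PDGF again raised PDGFB and lowered FBXO32 and PIM1. The protocadherin PCDH1 rose 20.6-fold (0.662 ± 0.363 to 13.7 ± 1.82 CPM, n = 3, log2 fold change 4.36, SE 0.29, adjusted p = 5.8e-06) and the transcription factor NFATC2 19.0-fold. PDGFB rose 17.1-fold (0.572 ± 0.159 to 9.84 ± 0.834 CPM), ELFN1 9.99-fold and the hormone STC1 9.62-fold. FBXO32 fell 8.39-fold (39.1 ± 9.91 to 4.67 ± 1.34 CPM), the BH3-only gene BBC3 5.48-fold and PIM1 5.37-fold. CCNG2, a cyclin of arrested cells, fell 4.99-fold (64.3 ± 4.63 to 12.9 ± 0.555 CPM) and the connective tissue growth factor CTGF 4.69-fold. In all, 1122 genes were higher and 757 lower. The total of 1879 was 4927 without library 16, with 1858 genes keeping call and direction, 1027 without library 11 and 1117 without library 14.

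ERK feedback regulators again rose, 15 higher and 4 lower of 27 (17 and 6 adjusted over the list alone, adjusted p = 1.7e-06, adjusted p = 0.0091 with an estimated correlation), ERRFI1 4.05-fold and SPRY2 3.73-fold among them. Inflammatory genes had 10 higher and 2 lower of 31 (12 and 3, adjusted p = 0.0035, adjusted p = 0.427 with an estimated correlation). Immediate-early genes had 9 higher and 7 lower of 30 (12 and 8, adjusted p = 0.0760, or 0.0440 without library 14 and 0.0346 without 17). The p53 and growth arrest list had 12 lower and 1 higher of 27 (14 and 1, adjusted p = 7.8e-08, adjusted p = 0.103 with an estimated correlation). Autophagy and lysosome had 8 lower and 0 higher of 42 (11 and 2, adjusted p = 3.7e-06, adjusted p = 0.367 with an estimated correlation). Library 16 enters as vehicle and held 28 of the 42 above both other members of its group, and without it 15 were lower and 2 higher while the median moved from -0.33 to -0.11. Interferon response had 3 lower and 0 higher of 32 (7 and 0, adjusted p = 4.7e-05, adjusted p = 0.453 with an estimated correlation). Quiescent stellate cell markers had 3 higher and 0 lower of 13 (5 and 0, adjusted p = 0.0064, adjusted p = 0.103 with an estimated correlation), with the adipogenic regulator PPARG at 13.1 ± 1.83 and 28.2 ± 1.18 CPM (2.15-fold). No collagen or matrix gene of 35 was called by edgeR, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05 by edgeR (adjusted p = 0.452 for the list). Library 16 held 28 of these 35 below both other members of its group, so this result depends in part on it.

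Several list results of this contrast rest on single libraries. YAP and SRF-MRTF targets had 5 lower and 0 higher of 25 (adjusted p = 0.0321, 0.0779 without library 10, 0.0516 without 14 and 0.0923 without 16, adjusted p = 0.367 with an estimated correlation). Cell cycle genes had 2 lower of 36 (1 adjusted over the list alone, adjusted p = 0.0159, 0.132 without library 13 and 0.0997 without 16, adjusted p = 0.427 with an estimated correlation). The stress response list had 6 lower and 2 higher of 29 (8 and 2, adjusted p = 0.0022, 0.121 without library 16, adjusted p = 0.427 with an estimated correlation). Oxidative phosphorylation (adjusted p = 0.0018, adjusted p = 0.616 with an estimated correlation) and ribosomal proteins (adjusted p = 3.5e-05, adjusted p = 0.586 with an estimated correlation) had 0 members called by edgeR, DESeq2 or limma-voom and 8 each at an unadjusted p under 0.05 by edgeR. Without library 16 they gave 0.760 in the other direction and 0.535. Synectin partners (adjusted p = 0.113) passed without libraries 10 (0.0489), 13 (0.0254) and 14 (0.0443), and cholangiocyte and epithelial markers (0.0899) without 14 (0.0443) and 16 (0.0107). Without library 16, sterol genes moved from 0.147 to 0.0384 and histone-modifying enzymes from 0.844 to 0.0193, with adjusted p = 0.600 and adjusted p = 0.363 with an estimated correlation (0.188 for the cholangiocyte and epithelial list). The remaining 9 lists ran from 0.0996 for hepatocyte markers to 0.910 for endothelial markers.

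The PDGF responses of the 2 arms, which share no library, correlated across genes at Pearson r = 0.60 (0.127 without the low-count filter) and Spearman rho = 0.46, with 836 genes higher and 459 lower in both, against 87.5 and 35.1 for independent lists, and 10 opposite. The arms share the fitted spread per gene, so here too independent lists are too low a reference.

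The PDGF response of HBEGF, MYC and other genes was smaller with synectin shRNA, tested directly as an interaction. HBEGF rose from 4.86 ± 0.271 to 121 ± 8.25 CPM in control cells and from 3.83 ± 0.892 to 14.5 ± 0.867 CPM in synectin shRNA cells (difference of log2 responses -2.71, SE 0.20, adjusted p = 0.00057, n = 3 per group). MYC went from 30.7 ± 1.78 to 86.7 ± 3.25 CPM in control and stood at 24.1 ± 2.37 and 27.1 ± 1.85 CPM in synectin shRNA cells (-1.33, SE 0.14, adjusted p = 0.0043). The stress cytokine GDF15 rose from 34.9 to 75.0 CPM in control and went from 53.2 to 24.2 CPM under synectin shRNA (-2.24, SE 0.20, adjusted p = 0.0014). INSIG1 rose from 35.6 to 82.4 CPM and stood at 6.97 and 5.43 CPM (-1.57, SE 0.18, adjusted p = 0.0089), and PMAIP1 rose from 27.6 to 64.6 CPM and stood at 70.3 and 56.2 CPM (-1.55, SE 0.16, adjusted p = 0.0043). These 5 genes stayed called without any 1 of the 12 libraries. IL11 (-2.33, SE 0.29) and ID3, an inhibitor of differentiation factors (-2.72, SE 0.35), lost their call only without library 4 (adjusted p = 0.0526 each). The opposite sign marked GAS1, a growth arrest gene (1.71, SE 0.23), which PDGF took from 13.1 to 2.66 CPM in control cells and from 5.32 to 3.53 CPM in synectin shRNA cells. It lost its call without library 4 (adjusted p = 0.0547).

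In all, 76 genes had a smaller or more negative response under synectin shRNA and 19 the reverse, 95 of 21344, with 1563 at an unadjusted p under 0.05. The count depended on single libraries: 805 without library 16, with the 95 genes keeping call and direction, but 29, 5 and 33 without control vehicle libraries 1, 4 and 7. It was 35, 39 and 20 without control PDGF libraries 2, 5 and 8, and 41, 41 and 35 without synectin shRNA PDGF libraries 11, 14 and 17. With a block of adjacent title numbers 4 of the 95 genes stayed called. GIPC1 (adjusted p = 0.727), PDGFRB (0.727) and PDGFRA (0.924) were not called.

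**Figure D4:**
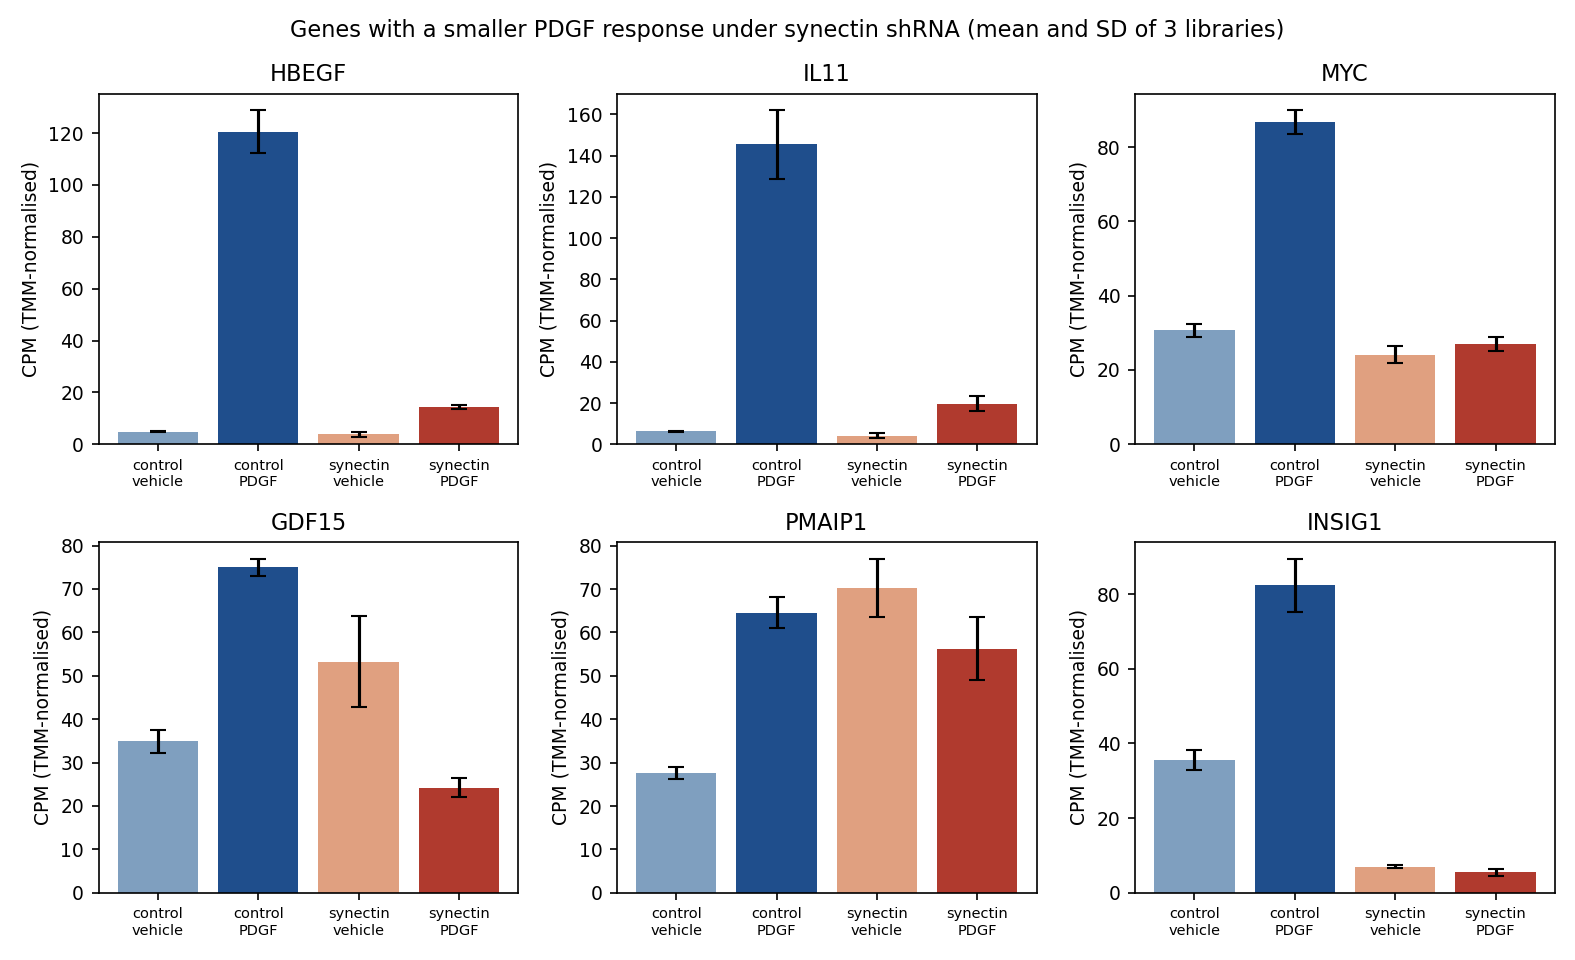
TMM-normalised CPM (vertical axes) of 6 genes called in the interaction, by group; bars are means and error bars 1 SD of 3 libraries. HBEGF reaches 121 CPM with PDGF under control shRNA and 14.5 CPM under synectin shRNA.

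Immediate-early, inflammatory and ERK feedback genes had smaller responses as groups, though these lists share some members. Immediate-early genes had 9 lower and 0 higher of 30 (21 and 0 adjusted over the list alone, adjusted p = 3.8e-21, adjusted p = 0.0024 with an estimated correlation). Inflammatory genes had 8 lower and 0 higher of 31 (18 and 0, adjusted p = 1.2e-19, adjusted p = 0.0091 with an estimated correlation, or 0.0555 without library 16), and ERK feedback regulators 9 lower and 0 higher of 27 (12 and 0, adjusted p = 7.3e-12, adjusted p = 0.0011 with an estimated correlation). Interferon response (adjusted p = 4.0e-07, adjusted p = 0.459 with an estimated correlation), YAP and SRF-MRTF targets (adjusted p = 0.0030, adjusted p = 0.153 with an estimated correlation) and sterol genes (adjusted p = 0.0057, adjusted p = 0.212 with an estimated correlation) also passed with a negative sign by the preset test. Matrix genes, the reverse in sign (adjusted p = 0.0014, adjusted p = 0.483 with an estimated correlation), did not pass without library 16 (0.187). The p53 and growth arrest list had 3 lower and 0 higher of 27 (6 and 5, adjusted p = 0.386), or 6 and 7 without library 16. Contractile genes had 1 lower, SRF (adjusted p = 0.134, or 0.0300 without library 16, where adjusted p = 0.509 with an estimated correlation), and the receptor and synectin lists none by edgeR, DESeq2 or limma-voom (0 and 1 at an unadjusted p under 0.05, adjusted p = 0.290 for both).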

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

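In this part, the tests of library 16 alone, of a ceiling on the level reached and of the PDGFRB level were chosen only after the result was seen. Results stand here because the response to PDGF differed between the shRNA arms by the interaction test itself. The rule for a single outlying value within a group needs at least 4 libraries, so it was not applied to these groups of 3.

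Among the named genes 29 differed, given as the log2 response under synectin shRNA minus that under control shRNA. The response was smaller or opposite in 23. Of secreted signals and inflammatory genes these were PTGS2 (-3.27), HBEGF (-2.71), interleukins IL6 (-2.36), IL11 (-2.33) and IL8 (-2.15), the stress cytokine GDF15 (-2.24), the chemokine CXCL3 (-1.85), urokinase PLAU (-1.35) and tissue factor F3 (-1.10). Of transcription factors and immediate-early genes they were ID3 (-2.72), CYR61 (-1.54), the mRNA decay factor ZFP36 (-1.53), MYC (-1.33), SOX9 (-1.15), IER2 (-1.07), SRF (-0.91) and PLK3 (-0.72). The phosphatases DUSP5 (-1.51), DUSP8 (-1.45) and DUSP1 (-1.30), the TGF-beta inhibitor SMAD7 (-1.01), INSIG1 (-1.57) and PMAIP1 (-1.55) complete them. The difference was positive in 6 genes: GAS1 (1.71), BMF (1.49), the ephrin receptor EPHB3 (1.45), DDIT4 (1.39), the nuclear receptor coactivator PNRC1 (1.20) and SMAD6 (1.09).

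Leaving out 1 library at a time, 5 of the 29 stayed called in every refit (HBEGF, MYC, GDF15, PMAIP1 and INSIG1) and 24 did not. The number lost was 24 without library 4 (adjusted p 0.0526 to 0.172), 18 without library 8 (0.0506 to 0.135), 14 without library 1 (0.0506 to 0.134) and 13 without library 7 (0.0570 to 0.177). It was 11 without library 2 (0.0543 to 0.126), 9 without library 17 (0.0532 to 0.113) and 8 each without libraries 5 (0.0526 to 0.134) and 11 (0.0563 to 0.103). It was 7 without library 14 (0.0509 to 0.109), 3 without library 13 (0.0599 to 0.0702) and 0 without libraries 10 and 16 by edgeR.

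As groups, 13 gene lists differed by the preset test and 3 of them also with an estimated correlation, the immediate-early (median -0.97), inflammatory (-0.92, adjusted p = 0.0555 with an estimated correlation and without library 16) and ERK feedback lists (-0.47). Interferon response (-0.77), sterol synthesis (-0.23) and YAP and SRF-MRTF targets (-0.22) passed the preset test alone. TGF-beta genes (-0.11, adjusted p = 0.0189, adjusted p = 0.416 with an estimated correlation) did not pass without libraries 7 (0.0600), 10 (0.154) or 13 (0.134). Autophagy and lysosome (-0.18, adjusted p = 0.0177, adjusted p = 0.4995 with an estimated correlation) did not without 1 (0.0611), 14 (0.0589) or 16 (0.294), nor cell cycle (-0.30, adjusted p = 0.0083, adjusted p = 0.459 with an estimated correlation) without 13 (0.134) or 16 (0.0807). Without library 16 the collagen and matrix list (0.19, adjusted p = 0.0014, adjusted p = 0.483 with an estimated correlation) gave 0.187 and cholangiocyte and epithelial markers (-0.52, adjusted p = 0.0061, adjusted p = 0.212 with an estimated correlation) gave 0.191. Oxidative phosphorylation (-0.55) and ribosomal proteins (-0.48), both at an adjusted p of 0.0014 and of 0.700 with an estimated correlation, turned to the other direction without library 16 (0.755 and 0.0272).

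The pattern weighed here is the smaller PDGF response of 76 of the 95 genes called, whose median response was 1.34 under control and 0.16 under synectin shRNA. Library 16 alone is argued against, since all 95 genes kept call and direction without it. A ceiling on the level reached is argued against only as the whole of it for the 76 genes as a set. Under PDGF their median log2 difference, synectin against control shRNA, was -0.77 (SE 0.125 over genes), beside 0.45 in vehicle. With PDGF, 64 of the 76 had every synectin shRNA library below every control library. They were picked for a lower response in these same libraries, which can pull the PDGF median down. For single genes a ceiling stays open, as PLAU reached 196 CPM in control and 213 CPM in synectin shRNA cells, and PLK3 40.0 and 45.9 CPM. The lower receptor level is a candidate explanation that stays open and cannot be told apart from other effects of the hairpin, since no synectin shRNA library exceeded 246 CPM of PDGFRB and no control library fell below 611 CPM. For the count of 95 the splits do not exclude chance, as 6 of 100 drawn from the 200 possible called as many genes, the highest other split 4133. The 5 others point to a structure of the samples, the PDGF response itself, since each keeps the control labels and exchanges 2 or 3 synectin shRNA libraries. Every split drawn that exchanged a control library called 0 genes by edgeR. Such an exchange puts the PDGF response of control cells into the spread, so that 0 is not a rate of false calls.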

How the results depend on the processing

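Only the limma-voom fit with sample quality weights was chosen after the results were seen. Of 438 results for named genes, DESeq2 and RLE factors changed no call, and limma-voom ended 3 calls, upper-quartile factors 8, library totals 12 and no low-count filter 21. The stricter filter changed no call among the 425 it could test. No alternative, leaving out a library included, turned the direction of a result called in the main fit or in the alternative. Signs of uncalled results were not compared, and some turned, as PDGFRA in the interaction (log2 difference 0.10, or -0.18 without library 16). Fits to the 6 libraries compared ended 38 calls of 379 results and gained 5, the block ended 38 of 237, and quality weights gained 13 of 438. Of the 98, 97, 86, 69 and 29 named genes called in the 5 comparisons, 92, 87, 72, 57 and 5 stayed called without any 1 library. Among the tests of 26 lists in 5 comparisons, RLE factors left 129 on their side of the threshold, upper-quartile factors and library totals 126 each, and no filter 122 of 130, and the stricter filter 113 of 120. The estimated correlation ended 37 calls, and fry ended 15 and gained 25. Without 1 library at a time, 1505 list results held, 31 were gained, 20 lost and 4 turned.

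Counts of genes called are given in the order knockdown in vehicle, knockdown in PDGF, PDGF in control and PDGF in synectin shRNA, then interaction. Fits to the 6 libraries compared gave 2271, 10933, 7485 and 411. Quality weights, at 0.0297 for library 16, gave 10701, 11690, 8313, 5708 and 1067. An adjusted p of 0.01 gave 3292, 2930, 1419, 934 and 6 and a fold of at least 2 gave 1867, 1740, 923 and 633, being stricter by construction. DESeq2 gave 2866 for PDGF in synectin shRNA and 301 for the interaction, where 29.6% of its calls on simulated counts were false. The block of adjacent title numbers left 4 for the interaction (2040 and 1303 for PDGF by arm). Deviations of libraries with adjacent numbers correlated at -0.026 to 0.190, and those of other pairs at -0.206 to 0.187. With 3 libraries per group these values cannot tell whether adjacent numbers share a culture, and the labels do not say. Leaving out 1 library gave 3898 to 9986, 3531 to 10858, 1579 to 7233, 1027 to 4927 and 5 to 805. The similarity of the knockdown effects ran from 0.602 to 0.743 without 1 library, 0.213 without a filter and 0.815 with the stricter one. That of the PDGF effects ran from 0.480 to 0.627, 0.127 and 0.709. Oxidative phosphorylation ran from 0.0041 to 0.340 for the knockdown in vehicle and turned without library 16 (0.0296). It ran from 3.4e-06 to 0.760 for PDGF in synectin shRNA and from 2.0e-06 to 0.755 for the interaction, and ribosomal proteins from 2.2e-07 to 0.0272 for the interaction, each highest value being the turned one without library 16. The 6-library fits that lack library 16 (knockdown in PDGF and PDGF in control) gave 10933 and 7485, near the 10858 and 7233 of the fit leaving it out. Those that hold it gave 2271 and 411, so this swing goes with library 16. Except for this and the stricter thresholds, the cause was not tested.

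On simulated counts at the depth of these libraries, edgeR recovered 81.6% of 4-fold, 29.2% of 2-fold and 0 of 86 1.5-fold differences for the interaction (7 by DESeq2 and 0 by limma-voom of the last). Their spread was that of all 12 libraries, given to each alike, so the real libraries may differ. Depth was not varied on its own.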

Other observations

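In this part, the 6 further gene groups were chosen after their values were seen, as were the tests of length and GC as the whole departure of library 16 and of base composition in genes without the motif, as a part and as the whole of the shift. Messages of replication-dependent histone genes normally lack a poly(A) tail, and which form was read here was not tested. These and related histone genes were higher with synectin shRNA. Of 37 tested, 29 were higher and 0 lower in vehicle (median log2 fold change 1.64, 25 to 32 higher without any 1 library). In PDGF 28 were higher and 0 lower (1.90, 20 to 34 without any 1 library). HIST2H2BE went from 9.30 to 48.0 CPM in vehicle, HIST1H2AC from 52.2 to 162 and HIST1H4H from 3.34 to 16.1 CPM, though near-identical copies can share reads. Metallothioneins, which bind zinc and copper, had 5 higher and 0 lower of 7 in vehicle (median 2.67, 5 without any 1 library) and in PDGF (1.63, 4 or 5 without any 1 library, with 1 lower without library 16). In vehicle MT2A averaged 109 and 482 CPM, MT1E 12.7 and 80.3 CPM and MT1X 2.81 and 21.7 CPM. Hedgehog targets had 7 lower and 1 higher of 12 in vehicle (6 to 9 lower without any 1 library), among them the receptor PTCH1 (53.05 to 12.97 CPM) and the transcription factor GLI1 (9.91 to 2.65 CPM). In PDGF they had 3 lower and 0 higher (3 to 6 lower and 0 to 3 higher without any 1 library). Under the other scalings 0 to 3 were higher there and the median ran from -0.13 to 0.03. With PDGF, histone genes had 6 lower and 0 higher in control (3 to 11 lower without any 1 library) and 3 lower and 0 higher in synectin shRNA cells (0 to 7 lower). Hedgehog targets with PDGF had 2 lower (2 to 4) and 1 higher (1 to 4) in control, and 2 lower (0 to 4) and 3 higher (2 to 4) in synectin shRNA cells.

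Targets of the FoxO transcription factors, which growth factor signalling through AKT holds out of the nucleus, fell with PDGF in both arms. Of 19 tested, 14 were lower and 1 higher in control cells (median -1.78, 12 to 17 lower without any 1 library) and 12 lower and 1 higher in synectin shRNA cells (-1.29, 12 to 16). FBXO32, TXNIP and BBC3, given above, belong to the group. The insulin receptor substrate IRS2 went from 30.0 to 9.30 CPM in control and from 21.3 to 9.39 CPM in synectin shRNA cells, KLHL24 from 53.4 to 12.7 and from 78.0 to 24.9 CPM, and PIK3IP1, an inhibitor of PI3 kinase, from 58.9 to 17.2 and from 58.1 to 20.9 CPM. With synectin shRNA, FoxO targets had 4 higher (1 to 8) and 6 lower (5 to 7) in vehicle and 8 higher (6 to 10) and 3 lower (2 to 5) in PDGF. Secreted growth factors had 9 higher and 1 lower of 21 with PDGF in either arm (8 to 11 higher and 1 or 2 lower in control and 5 to 9 higher and 1 to 5 lower in synectin shRNA cells without any 1 library), and 2 higher and 5 lower in vehicle and 1 higher and 9 lower in PDGF with synectin shRNA. VEGFA, which drives vessel growth, went from 81.3 to 169.9 CPM with PDGF in control cells and was 38.4 CPM in synectin shRNA cells in vehicle. Clock genes went both ways, 4 higher (2 to 11) and 2 lower of 16 with synectin shRNA in vehicle, 6 (2 to 9) and 3 in PDGF, and with PDGF 5 (3 to 8) and 4 in control and 2 (1 to 4) and 4 in synectin shRNA cells.

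Genes with the sequence ATTTGCC in the 3' UTR were lower with synectin shRNA, a pattern found by ranking all 16167 heptamers on the same data. It stood in 1517 of 12248 protein-coding genes searched (97.0% of those expressed, a restriction made after 76.9% of genes of any type proved searchable), whose mean log2 shift after UTR length and GC was -0.26 in vehicle and -0.26 in PDGF (z -17.6 and -18.3, lowest of all in both), against z 0.54 and 0.29 for PDGF in the 2 arms. Base composition as the whole of it is argued against, since in genes without ATTTGCC the 417 other orderings of its bases had a median shift of 0.064 in vehicle and 0.065 in PDGF (SD 0.032 and 0.030), but a part stays open, as the lowest reached -0.077 (SE 0.064) in PDGF and, in all genes, TTGCCAT, which shares 5 bases with it, z -8.08. A small RNA that pairs with the sequence may act on these genes, since those with 2 or more sites were lower by a further -0.14 (SE 0.048) in PDGF, and those with a site in the coding part alone were at -0.040 in PDGF but -0.13 in vehicle, where 1 site in the 3' UTR gave -0.24, which keeps it open. Whether it would be a hairpin product or a cell's own small RNA was not tested. The z and SE of these shifts are over genes and not over libraries. The GIPC1 transcript searched holds neither ATTTGCC nor its reverse complement GGCAAAT. In vehicle the site stood in 25.7% of genes called lower and 6.24% of those called higher, against 12.4% of all searched. By list it stood in 0 of 29 stress response and 0 of 29 interferon genes. It stood in 2 of 18 contractile, 3 of 31 sterol and 2 of 25 inflammatory genes. The counts were 6 of 25 YAP and SRF-MRTF targets, 6 of 30 matrix enzyme genes and 3 of 10 of the most lowered named genes. Of named lowered genes, SRF, DAP and SOD2 held 1 site, SETD7 3 and GREM1 4. ACTA2, LMOD1, INSIG1, SREBF2, HBEGF and PDGFRB held 0. PHLDA1 and PLAU, both higher in vehicle, held 1 each. Whether the site or the loss of synectin lowered SRF and GREM1 was not tested.

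Library 16 stands apart from libraries 10 and 13 of its group (r = 0.958 and 0.961 on log2 CPM, other pairs within groups 0.991 to 0.993), with ribosomal protein genes at a median log2 difference of 1.23 and oxidative phosphorylation genes at 1.24. Cells without the knockdown are argued against, since genes that fall at least 4-fold with synectin shRNA lay at a median of -0.04 (SE 0.12 over 63 genes) where the share read from GIPC1 would give 0.83. Hepatocytes and leukocytes are argued against as well. Their summed markers, led by CPS1 (10.6 CPM) and CD68 (14.4 CPM), were 14.0 and 16.0 CPM, against 13.5 and 15.3 CPM in the lowest other library. These sums were 0.551 and 0.658 times the highest other library, and ALB and PTPRC stood at 0.0898 and 0.0359 CPM. For endothelium the ratio of 1.06 cannot decide, since its sum of 53.4 CPM lay above the 36.4 to 50.4 CPM of the others. CLEC14A stood at 14.0 CPM against 8.10 CPM in libraries 10 and 13, and VWF at 0.862 CPM. For cholangiocytes the ratio of 0.521 cannot decide, because SOX9 of that list rises with PDGF. The summed list was 278 CPM in library 16 and 174 to 534 CPM in the others. KRT18 stood at 126 CPM against 66.3 CPM in libraries 10 and 13, the list median lay 0.60 higher than there, and EPCAM stood at 1.45 CPM. A bias of gene length and GC explains 20.5% of the variance of its deviation. The share is like that of library 7 (22.7%) and library 1 (17.2%), but of a far larger deviation (SD 0.837 against 0.203 and 0.172, log2 scale). Its slope per doubling of length was -0.190, against -0.035 and 0.025 there. Genes with a coding length under 1000 bp held 5.80% of its reads, against 4.33% and 4.43% in libraries 10 and 13. The bias is not the whole of the departure, since mean r with libraries 10 and 13 went only from 0.934 to 0.952. These r are over the genes of this fit (mean of at least 1 CPM, with length and GC), where the lowest other pair had 0.994. As a part it stays open, because on coding transcripts alone, the source of GC used at the start and replaced, after its value was seen, for covering only 78.2% of genes, the curve explained 38.2%, and no biological difference of this sample was tested.

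For the other comparisons the splits of 6 libraries are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, called as many genes: 5693 for the knockdown in vehicle, 5063 for the knockdown in PDGF, 2655 for PDGF under control and 1879 under synectin shRNA, with 0 in the highest other split. Every other split mixes both real groups on each side, which puts their difference into the spread. Its 0 is therefore not a rate of false calls.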
